A study of Homo sapiens with 2 samples.

How the data were processed

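Messenger RNA was measured on 2 CodeLink oligonucleotide arrays of 1 colour each, with biotin-labelled cRNA detected with Cy5, per the labels. One array was hybridised with RNA of normal bone marrow mononuclear cells (NBM) and the other with RNA of giant multinucleated osteoclasts enriched from osteoclastoma, the giant cell tumour of bone (GCT-OCL). Per the labels, each array carried a pool of 3 samples, and the osteoclasts were enriched with 23C6, a mouse monoclonal antibody to the alpha V beta 3 integrin. Each group therefore had 1 array, and the number of arrays limits the precision: differences between samples within a pool were not measured. No test, p-value or standard error was possible. Batch of hybridisation or scan and group cannot be told apart, since each group had 1 array.

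The deposited scanner output gave each spot as an intensity, the mean of its pixels and the median of its local background, per the file headers. The authors' software also gave a background-subtracted intensity, which equalled spot mean minus background median, and a normalized intensity, which was the former divided by 1 constant per array (60.5 for NBM and 54.8 for GCT-OCL). Per the file headers, the authors normalized intensities to the median of the array. The deposited value matrix held the authors' normalized intensities of 21492 probes, rounded and with a floor of 0.01. Its medians were 1.47 for NBM and 1.41 for GCT-OCL. It was on a linear scale, not centred by gene, with NBM and GCT-OCL in separate columns; above 1, its values were 1.015 times the scanner software's normalized values for NBM and 1.014 times for GCT-OCL, and the origin of these factors stays unknown. The authors' deposited table gave the ratio of the GCT-OCL over the NBM value for the same probes and, per the file headers, listed genes over 2-fold in at least 1 sample against bone marrow. The 2 columns of normalized values in that table were not used. A deposited gene ontology table was not used here. The version of the scanner software is not given in the sources used here.

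Background was corrected with normexp on the spot mean and background median with an offset of 50 in limma 3.58.1 under R 4.3.3. Control spots (384 negative and 360 positive) were left out after that step, the 53423 remaining probes were quantile normalized between the arrays, and the log2 was taken. The scanner software's quality flags decided which probes were above background. Probes with flags other than above background, saturated or near background were left out, which removed 575 probes and left 52848 usable on both arrays. Of 16436 probes with a RefSeq transcript accession, 15228 (92.7%) were matched without version numbers to a RefSeq gene table of GRCh38.p14, which served for names only. The other 38195 probes stayed unnamed. Probes of a gene were averaged on the log2 scale, giving 14077 genes. A gene was above background on an array if at least 1 of its probes was.

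The comparison was the log2 signal of GCT-OCL minus that of NBM. Its size was counted at 2-fold among genes above background on at least 1 array. The offset makes the differences of dim genes smaller than they were. For a gene not above background on 1 array, the fold is written as at least N-fold, against the higher of its own signal and the lowest signal of probes above background there; a gene saturated on 1 array is also given as at least N-fold, and a gene saturated on both has no fold. The only measure of spread was the SD of the difference between probes of 1 gene, 0.56 on the log2 scale (1.48-fold) over 781 genes with several probes. It comes from different probes on the same 2 arrays, so it holds no variation between arrays that all probes share. Probes differed by over 2-fold for 109 of these genes, and for 2 genes they lay at least 2-fold in opposite directions.

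The 26 gene lists, the rule for named genes and the main settings were fixed before the data were examined. Each list was described by the median log2 difference of its members above background and by the percentile of that median among 10000 random lists of the same size matched on mean signal. A list is said to stand apart when the percentile lies under 2.5 or over 97.5. This describes these 2 arrays and is no test across samples. The rule named the 12 genes with the largest difference in each direction among genes above background and unsaturated on both arrays; the 6 with the largest lower bound in each direction among genes above background on 1 array only; up to 4 members of each list with the largest difference; and in every case ITGAV, ITGB3, CTSK, ACP5, MMP9, CALCR, TNFRSF11A, NFATC1, TNFSF11, ACTB and GAPDH. Names without a standard symbol were passed over, and variable immune receptor segments and genes that differ between people by common deletion or polymorphism were never named. Some members under this rule are left out of the text, and a few genes are not reported here. Genes named outside it are said to be chosen after their values were seen.

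The calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data, a pair of arrays of 14112 genes with 200 changed genes. Genes simulated 4-fold higher came out at a median of 3.32-fold and those 16-fold higher at 13.9-fold (25 genes each). Genes simulated 4-fold lower came out at 2.81-fold and those 16-fold lower at 5.11-fold (25 genes each). All changed genes started at a middle signal and only the second array was changed, so the lower ones ended dim. On the real arrays stromal genes were dim on NBM (median log2 signal 6.7) and neutrophil genes bright (12.92). Folds of higher genes can thus be shrunk too, and the simulated difference between directions does not carry over. At the 2-fold threshold, 7 of 25 genes simulated 2-fold higher and 4 of 25 simulated 2-fold lower were counted, and 0 of 11769 unchanged genes were. Both simulated arrays were drawn from the NBM signal with less noise than the spread between probes of 1 gene. The 0 is therefore no rate of false counts for the real arrays.

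Alternatives were an offset of 16, no background correction, plain subtraction with a floor, scaling to the median or to the 75th percentile in place of quantile normalization, the authors' value matrix, the brightest probe of a gene, only probes above background on both arrays, no filter on dim genes, and a threshold of 4-fold. Chosen after seeing the data were the authors' normalized values of all probes, the names of the authors' table for 1397 further probes, leaving out saturated probes, and counting genes not above background on 1 array at their bound. All other counts use the measured difference.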

Results

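Expression was compared between a preparation enriched for osteoclasts, the multinucleated cells that resorb bone, and marrow mononuclear cells. The GCT-OCL array held RNA of giant osteoclasts enriched from osteoclastoma with an antibody to the alpha V beta 3 integrin, and the NBM array RNA of normal bone marrow mononuclear cells. Each group had 1 array made from a pool of 3 samples, so no difference has a replicate check, and all values below describe these 2 arrays. Of 53423 probes, 35869 (67.1%) were above background on the NBM array and 35128 (65.8%) on the GCT-OCL array. The median background-subtracted intensity was 59.8 on NBM and 54.2 on GCT-OCL, against 5.73 and 5.65 for negative control spots. On each array 24 probes were saturated.

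The comparison asks which transcripts were more or less abundant in the enriched preparation than in marrow cells. The purity of the preparation is not given, so a higher signal does not tell which of its cells held the RNA. Genes of bone resorption, stromal cells and bone matrix were mostly higher in GCT-OCL, and genes of granulocytes and red cell precursors mostly lower. Of 12647 genes above background on at least 1 array, 1873 (14.8%) were at least 2-fold higher in GCT-OCL, 1242 (9.82%) at least 2-fold lower and 9532 under 2-fold. At least 16-fold differences were found for 108 genes higher and 99 lower. The median log2 difference over all genes was 0.12. Across genes, which are not independent replicates, the signals of the arrays correlated with Pearson's r of 0.747 and Spearman's rho of 0.736. With the authors' normalized values of all probes, which carry no offset, 2868 genes were at least 2-fold higher and 1725 at least 2-fold lower.

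**Figure D1:**
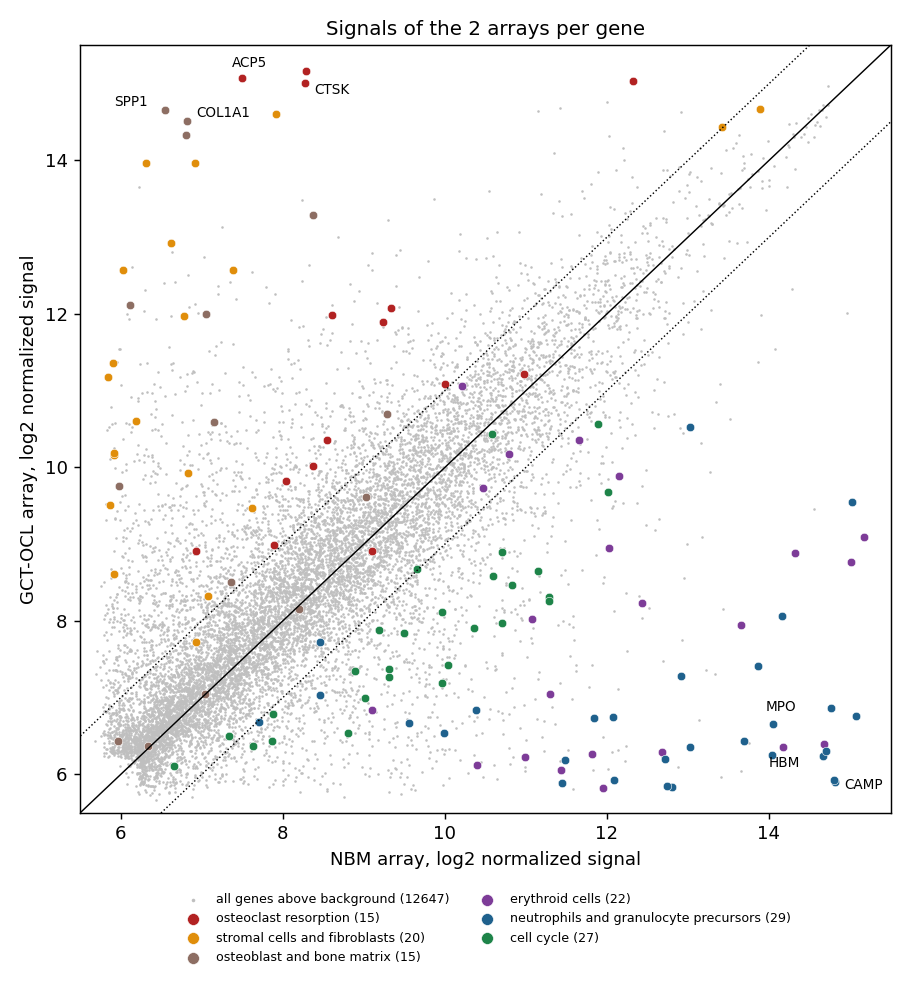
Each point is a gene, with its log2 normalized signal on the NBM array on the horizontal axis and on the GCT-OCL array on the vertical axis. Grey points are the 12647 genes above background, coloured points are members of 6 gene lists, the solid line marks equal signal and the dotted lines 2-fold. Neutrophil genes such as CAMP lie far below the line, and ACP5, CTSK, SPP1 and COL1A1 far above it.

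Osteoclast genes were higher in GCT-OCL. Of 15 genes of bone resorption above background, 13 were at least 2-fold higher and 0 lower (median log2 difference 1.97, percentile 100). ACP5, the tartrate-resistant acid phosphatase used as an osteoclast marker, was at least 192-fold higher, and CTSK, the protease that degrades bone collagen, at least 107-fold. CKB, a creatine kinase, was at least 119-fold higher, MMP9 at least 6.55-fold and MMP14 10.3-fold. ACP5, CTSK, CKB and MMP9 were saturated on the GCT-OCL array. TCIRG1, a subunit of the proton pump of the resorbing membrane, was 6.7-fold higher, CA2 3.93-fold and CLCN7 3.14-fold; these 3 genes were chosen after their values were seen.

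Of 22 genes of osteoclast differentiation and fusion, 13 were higher and 1 lower (median 1.24, percentile 100). SIGLEC15, a receptor of the osteoclast surface, was 72.7-fold higher, CSF1R, the receptor of macrophage colony-stimulating factor, 20.1-fold, RUFY4 11.8-fold and NFATC1, the main transcription factor of osteoclast formation, 9.62-fold. TNFRSF11A, which encodes RANK, was at least 4.58-fold higher and CALCR, the calcitonin receptor, at least 5.02-fold, since neither was above background on NBM. The gene that was lower was NHERF1 (4.08-fold), chosen after its values were seen. ITGAV was 12.3-fold and ITGB3 5.08-fold higher (median 2.98, percentile 99.2); they encode the antigen by which the cells were selected, so this is no finding, and in the authors' value matrix the list did not stand apart.

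Subunits of the V-ATPase, the proton pump of lysosomes and of the resorbing membrane, were higher for 12 of 18 genes and lower for 1 (median 1.72, percentile 100). ATP6V1B2 was 8.35-fold higher and ATP6V1A 5.38-fold, while ATP6V0A1, chosen after its values were seen, was 2.23-fold lower. Among 26 genes of lysosomal proteins, 15 were higher and 2 lower (median 1.15, percentile 100). GPNMB was 13.6-fold, LGMN 6.97-fold and CTSB 5.51-fold higher. The lower members were the cathepsins CTSS (3.31-fold) and CTSH (2.45-fold), chosen after their values were seen. Stromal markers were higher on the same array by a larger median, 4.34.

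**Figure D2:**
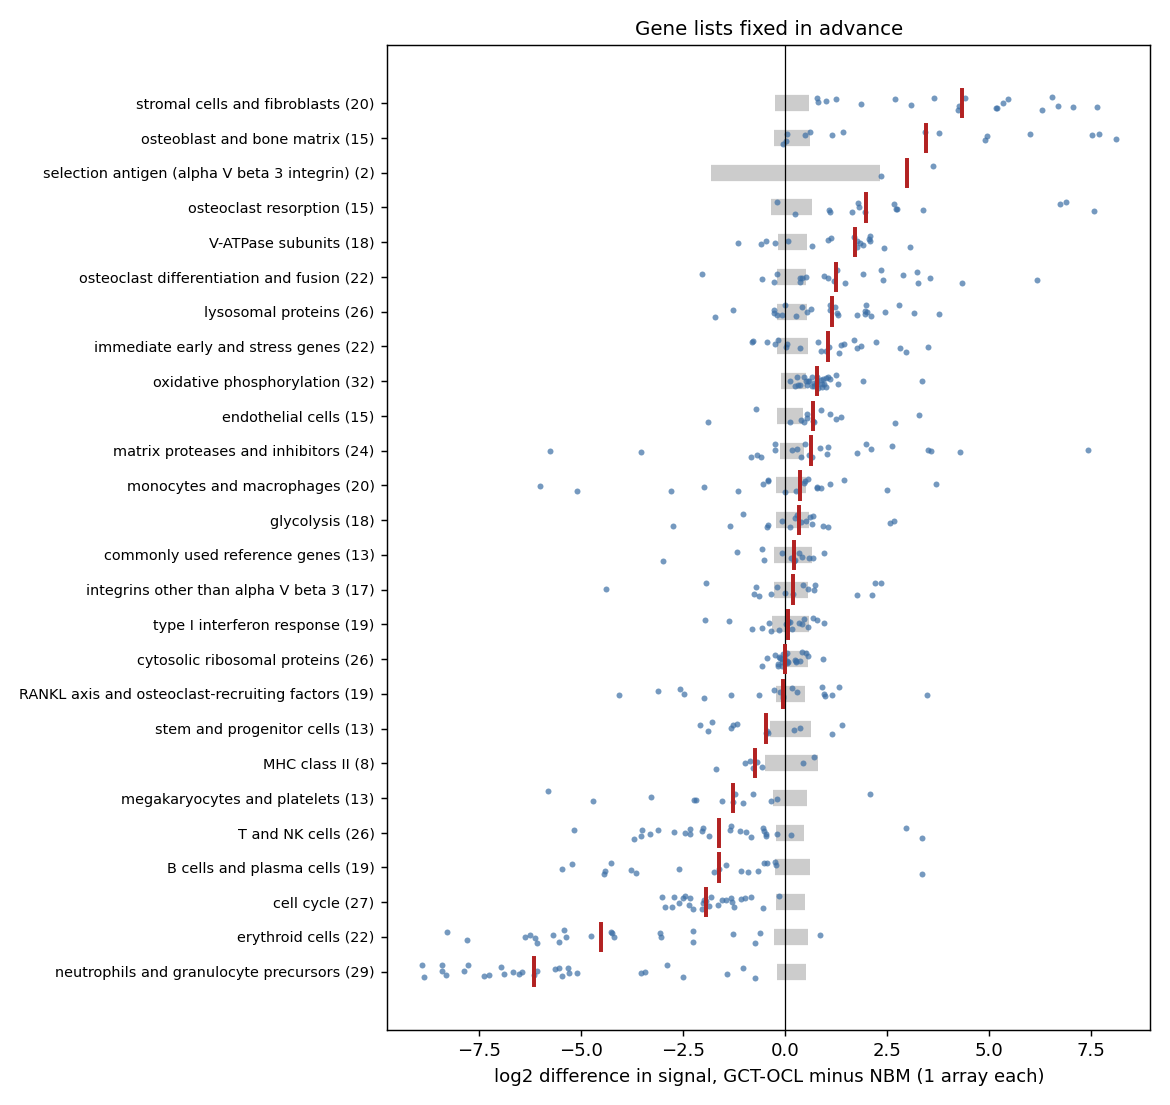
Each blue point is a gene above background, placed by its log2 difference in signal, GCT-OCL minus NBM, in the list named on the left with its number of genes. Red bars are list medians, and grey bars span the range outside which a list was said to stand apart, from the medians of 10000 random lists matched on mean signal. Medians run from -6.16 for neutrophils to 4.34 for stromal cells.

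Genes of connective tissue and bone matrix were also far higher in GCT-OCL. Of 20 stromal and fibroblast genes, 18 were higher and 0 lower (median 4.34, or 4.23 with genes not above background on 1 array at their bound; percentile 100). COL3A1, a fibrillar collagen, was 201-fold higher, the proteoglycans LUM 132-fold and DCN at least 103-fold, POSTN at least 85.8-fold and COL6A2 78.4-fold. Of 15 osteoblast and bone matrix genes, 10 were higher and 0 lower (median 3.44, percentile 100). SPP1, which encodes osteopontin, had the largest difference among genes above background and unsaturated on both arrays, 277-fold. COL1A1 was at least 209-fold, COL1A2 184-fold and IBSP at least 62.5-fold higher. With the 2 probes named COL1A2 only in the authors' table added, its log2 difference was 4.09 instead of 7.52. In the authors' deposited table the GCT-OCL over NBM ratio was 694 for SPP1 and 426 for COL1A1. SPP1 is also known to be made by osteoclasts.

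Matrix proteases and their inhibitors were higher for 10 of 24 genes (9 with genes not above background on 1 array at their bound) and lower for 2 (median 0.62, percentile 99.9). The collagenase MMP13 was 173-fold and MMP2 11.9-fold higher. The lower members were MMP8, the neutrophil collagenase, at least 42.1-fold, and MMP25, 11.6-fold, which also belongs to the neutrophil list and was chosen after its values were seen. Other genes among those with the largest differences were IGFBP6 (64.8-fold), PCOLCE, an enhancer of procollagen processing (59-fold), OLFML2B (58.2-fold), SDC2 (53.8-fold) and IRX3 (53.8-fold). HTRA1 was at least 87.8-fold, CXCL14 at least 57.8-fold, SFRP4, a secreted Wnt inhibitor, at least 55.1-fold and PDLIM4 at least 41.9-fold higher.

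Genes of marrow blood cell lineages were lower in GCT-OCL. Of 29 neutrophil and granulocyte precursor genes, 28 were lower and 0 higher (median -6.16, percentile 0). The granule protein genes CAMP and LTF were at least 397-fold and at least 392-fold lower, AZU1 at least 345-fold, PRTN3 221-fold and MPO, which encodes myeloperoxidase, 168-fold. Also among the largest differences were PADI4 (163-fold lower), PGLYRP1 (153-fold), LCN2 (at least 86.3-fold), PRG2 (88.0-fold), ANXA3 (86.5-fold), DEFA4 (68.6-fold) and TCN1 (58.3-fold). S100A12 was at least 341-fold lower, S100P at least 177-fold, RETN at least 149-fold and ORM1 at least 104-fold. Of 22 erythroid genes, 19 were lower and 0 higher (median -4.51, percentile 0). The globin genes HBD and HBM were at least 313-fold and 223-fold lower, HBB at least 76.1-fold, and ALAS2, the first enzyme of heme synthesis in red cell precursors, 83.5-fold.

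Lymphoid genes were lower as well. Of 19 B and plasma cell genes, 12 were lower and 1 higher (median -1.63, percentile 0). JCHAIN was 44.3-fold, CD24 37.2-fold, CD79B 21.9-fold and TCL1A 21.3-fold lower. With a probe named JCHAIN only in the authors' table added, its log2 difference was -2.93 instead of -5.47. Of 26 T and NK cell genes, 16 were lower and 2 higher (median -1.62, percentile 0). NKG7 was 36.1-fold, GZMK 13.2-fold, GZMA 11.7-fold and KLRB1 11.5-fold lower. Megakaryocyte and platelet genes were lower for 9 of 13 (8 with genes not above background on 1 array at their bound) and higher for 1 (median -1.27, percentile 0), with PPBP 56.5-fold, NFE2 at least 22-fold and PF4 at least 8.89-fold lower (log2 difference -1.77 by its 1 probe above background on both arrays). The higher member was THBS1 (4.21-fold), chosen after its values were seen. Of 13 stem and progenitor genes, 6 were lower and 2 higher (median -0.46, percentile 1.435). FLT3 was 4.28-fold and LMO2 3.47-fold lower, while SPINK2 was 2.63-fold higher, as was SOX4 (2.23-fold), chosen after its values were seen.

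Monocyte and macrophage genes went both ways, with 4 of 20 higher and 5 lower, and the list did not stand apart (median 0.37, percentile 89.8). CD68, a lysosomal glycoprotein of macrophages and osteoclasts, was 12.9-fold higher. FCN1 was 64.9-fold, LYZ, which encodes lysozyme, 34.5-fold and FCGR1A 6.96-fold lower. Also higher were APOE (5.63-fold) and C1QC (2.73-fold); these and the other lower members, CD14 (3.99-fold) and CX3CR1 (2.24-fold), were chosen after their values were seen. MHC class II genes stood apart on the lower side (median -0.75, percentile 0.57), although 1 of 8, HLA-DOA (3.22-fold), reached 2-fold; in the authors' value matrix this list did not stand apart. HLA-DRA was 1.74-fold lower.

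Factors of the RANKL axis and of osteoclast recruitment did not stand apart (median -0.06, percentile 16.6), with 3 of 19 higher and 6 lower. TNFSF11, which encodes RANKL, was 11.1-fold higher. Which cells of the preparation held this RNA was not measured. IL1B was 16.9-fold, the chemokine CXCL12 8.71-fold and CCL4 6.02-fold lower. PTHLH (2.48-fold) and TNFSF10 (2.24-fold), chosen after their values were seen, were the other higher members. Integrins other than alpha V beta 3 did not stand apart either (4 of 17 higher, 2 lower; median 0.20, or -0.01 over probes above background on both arrays; percentile 65.0). ITGB1 was 5.06-fold, ITGA5 4.41-fold and ITGA1 at least 3.9-fold higher, and ITGAM, an integrin chain of myeloid cells, 21.1-fold lower. ITGA8 (at least 3.22-fold higher) and ITGB2 (3.83-fold lower) were chosen after their values were seen. Endothelial genes were higher for 5 of 15 and lower for 1 (median 0.69, percentile 99.8). Most were dim, with median log2 signals of 6.28 on NBM, close to background, and 6.80 on GCT-OCL. ENG was 9.8-fold, PLVAP 6.49-fold and CLDN5 2.59-fold higher, ERG was 3.69-fold lower, and CDH5 (at least 2.36-fold) and TIE1 (2.15-fold), chosen after their values were seen, completed the higher members.

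Cell cycle genes were lower in GCT-OCL for 23 of 27 and higher for 0 (median -1.94, percentile 0). CCNB2, a mitotic cyclin, was 8.09-fold, AURKB, a mitotic kinase, 7.79-fold, NUSAP1 6.88-fold and CCNA2 6.63-fold lower. The erythroid list was lower on the same array by a larger median, -4.51. Oxidative phosphorylation genes were higher for 7 of 32 and lower for 0 (median 0.77, percentile 99.99), with NDUFA8 10.2-fold, NDUFB5 3.77-fold and COX4I1 2.44-fold higher; this list did not stand apart in the authors' value matrix. Glycolysis genes did not stand apart (3 of 18 higher, 3 lower; median 0.34, percentile 81.1). ENO2 was 6.32-fold and PFKP 5.92-fold higher, and HK3, a hexokinase, 6.69-fold and the glucose transporter gene SLC2A1 2.56-fold lower. PGAM1 (2.06-fold higher) and SLC2A3 (2.05-fold lower) were chosen after their values were seen.

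Immediate early and stress genes were higher for 12 of 22 and lower for 0 (median 1.05, percentile 100). HMOX1, which encodes a heme-degrading enzyme, was 11.3-fold, IER3 7.86-fold, the heat shock gene HSPA1B 7-fold and EGR1 4.66-fold higher. The type I interferon response did not stand apart (0 of 19 higher, 2 lower; median 0.07, percentile 38.1), with HERC5 3.93-fold and MX2 2.63-fold lower. None of 26 ribosomal protein genes reached 2-fold (median 0.00, or 0.15 with the authors' normalized values of all probes, percentile 7.495). Their median log2 signals were 14.1 on NBM and 13.88 on GCT-OCL. Saturated COL1A1 lay at 14.52 on GCT-OCL, so there was little room for a rise. Commonly used reference genes did not stand apart (0 of 13 higher, 2 lower, median 0.22, percentile 60.8). Their median was -1.04 in the authors' value matrix, which holds only probes the authors selected. With the authors' normalized values of all probes it was 0.37. TUBB was 2.26-fold lower. ACTB was 1.48-fold lower, about the SD between probes of 1 gene (1.48-fold), and GAPDH was saturated on both arrays.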

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

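All tests in this part were chosen after the result was seen. Probes without a gene name carried signal outside the gene comparison. Of 23420 unnamed probes above background, 1142 were at least 2-fold higher in GCT-OCL and 1688 at least 2-fold lower, 12.1% in all. Positive control spots had a median intensity of 25.5 on the GCT-OCL array and 21.4 on the NBM array, above the negative control medians of 5.65 and 5.73. They were dimmer than the median probe, at 54.2 on GCT-OCL and 59.8 on NBM.

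The authors' deposited table of 2-fold probes also held 8004 probes (37.2%) under 2-fold in this comparison. A choice at 2-fold on this ratio alone would have left these probes out, so they argue against it. Which other samples or values entered the table is not given and stays open. Among 18721 probes outside it and above background on both arrays, 24 (0.128%) reached 2-fold on the authors' values, but a choice at 2-fold fixes that share whatever other samples entered. A table of the whole array is argued against by the 31931 probes missing from it. No biological explanation was tested. Of the probes in the table, 3011 were near background on both arrays, and 1156 of those had an authors' ratio of at least 2-fold.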

How the results depend on the processing

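No named gene with a difference of at least 2-fold turned direction under any setting that gave it a value, and no list that stood apart turned direction. Of 128 named genes, 65 moved by at least the SD between probes with plain subtraction, 65 with the authors' values of all probes and 47 with an offset of 16, as did 64 of 120 in the value matrix, all further from 0. With the names of the authors' table added, COL1A2 (4.09) and JCHAIN (-2.93) moved nearer 0 and ITGB3 (3.11) further. With the brightest probe, NFATC1 (4.08) and PF4 (-4.83, by a probe not above background on GCT-OCL) moved further from 0, and over probes above background on both arrays PF4 (-1.77) nearer. Which lists stood apart was the same for 26 of 26 in each setting that was run for the lists but the authors' value matrix, where it was 23: the selection antigen, MHC class II and oxidative phosphorylation lists no longer stood apart. The 4-fold threshold and the setting without a filter on dim genes were run for the counts alone. That matrix holds only probes the authors selected, and its median over all genes was 0.66, against 0.12 in the main setting. Chosen after seeing the data were the authors' normalized values of all probes, the added names of the authors' table, leaving out saturated probes, and counting dim genes at their bound. In the value matrix 2914 of 6243 genes were at least 2-fold higher and 1768 lower. With the authors' values of all probes 2868 of 12647 were higher and 1725 lower. At 4-fold, 658 genes were higher and 457 lower. With genes not above background on 1 array at their bound, 1846 were higher and 1226 lower. The folds of dim genes depend on the offset and the floor.

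With an offset of 16 the median was 5.41 for stromal, -5.37 for erythroid and -6.78 for neutrophil genes. With plain subtraction it was 2.64 for osteoclast resorption, 4.08 for bone matrix, 6.05 for stromal, -5.83 for erythroid, -7.25 for neutrophil, -2.28 for B cell, -2.24 for megakaryocyte and 1.52 for endothelial genes. In the value matrix it was 2.87 for osteoclast resorption, 3.12 for osteoclast differentiation, 5.63 for bone matrix, 6.73 for stromal, 1.90 for protease, -6.02 for erythroid, -8.37 for neutrophil, -3.87 for B cell, -3.12 for T and NK cell, -1.22 for stem cell, -2.42 for megakaryocyte, 1.83 for endothelial and -1.04 for reference genes. With the authors' values of all probes it was 2.66 for osteoclast resorption, 1.87 for osteoclast differentiation, 4.13 for bone matrix, 6.74 for stromal, -5.75 for erythroid, -8.34 for neutrophil, -2.27 for B cell, -2.54 for T and NK cell, -2.30 for megakaryocyte and 1.72 for endothelial genes. Over probes above background on both arrays it was 2.43 for bone matrix and -5.56 for neutrophil genes; without saturated probes 2.43 and -5.60; with the added names 2.57 for bone matrix. All other list medians lay within 0.56 of the main value, the SD between probes of 1 gene. The cause was not tested beyond what each setting leaves out. No paired analysis was possible because each group has 1 array.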

Other observations

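All genes, families and tests in this part were chosen after their values were seen. Of 21 collagen genes outside the fixed lists, 9 were at least 2-fold higher in GCT-OCL and 4 at least 2-fold lower by the measured difference (median log2 difference 0.68, percentile 99.9, median over the settings 0.53 to 2.61). COL4A1, a basement membrane collagen, was at least 34.8-fold and COL11A1 at least 18.6-fold higher. At their bound 3 stayed at least 2-fold lower, COL17A1 (at least 3.51-fold), COL9A3 (3.01-fold) and COL9A2 (2.91-fold), while COL23A1 was at least 1.76-fold lower. Of 15 complement genes, 8 were higher and 2 lower (median 1.45, percentile 100). C1S was 24-fold, CFI 20.8-fold and C1R 20.4-fold higher, while CFP, which encodes properdin, was 24.9-fold and CFD 5.93-fold lower. Of 4 metallothionein genes, 3 were higher (median 2.66, percentile 99.92), namely MT1G (16.9-fold), MT1H (at least 10.4-fold) and MT1X (3.05-fold).

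Genes named BMP, GDF or inhibin beta were higher for 9 of 19 and lower for 0 without standing apart (median 0.35, percentile 92.2). The set was taken by name and includes BMP1 (3.2-fold higher), which is a protease and not a growth factor of this family. INHBB was 7.79-fold and BMP2 7.43-fold higher. S100A genes (median 0.41, percentile 88.3) and chemokine genes (median -0.12, percentile 5.675) did not stand apart. Of 25 chemokine genes, 3 were higher and 7 lower, with CXCL5 12.9-fold higher. Against the direction of the lymphoid lists, CD4 was 7.85-fold, KLRD1 10.2-fold and the plasma cell marker SDC1 10.2-fold higher. TNFRSF12A was 33.5-fold higher, and MKI67, the usual proliferation marker, was 1.1-fold lower. Probes named only through the authors' deposited table put FN1, saturated on GCT-OCL, at least 236-fold, TIMP3 52.6-fold, the osteoclast exchanger SLC9B2 47.7-fold and ATP6V1C1 10.3-fold higher. SPARC was 30.1-fold higher by its RefSeq probes, but a probe named SPARC only in that table was 4.35-fold lower. A probe named CD4 only in that table, not above background on NBM, had a log2 difference of 0.35.

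Stromal and bone matrix genes were high in a preparation selected for osteoclasts. Among abundant stromal transcripts, the log2 signal was 7.92 on NBM and at least 14.61 on GCT-OCL for DCN, which was saturated there, 6.92 and 13.97 for LUM, and 6.31 and 13.96 for COL3A1. S100A4 and VIM of the same list were also high on NBM, at 13.89 and 13.42. The osteoclasts were enriched with 23C6, but the purity of the preparation is not given in the sources used here. None of the 23 genes of this list is in another list, which does not tell which cells the RNA came from. The median of the stromal list was 4.43 without background correction and 4.38 with median scaling in place of quantile normalization. Its lowest median over all settings was 4.13, so it did not rest on the choice among these settings. Settings with a smaller offset could only enlarge it, so they were no check on its size. RNA of stromal cells and matrix genes transcribed by the osteoclasts themselves cannot be told apart here. The preparation was measured as a whole, so high signals would follow from either.

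Cell cycle genes were lower in GCT-OCL. Their median was -2.00 without background correction and -1.96 with median scaling in place of quantile normalization. The highest median of the list over all settings was -1.94, the main value, so its direction did not rest on the choice among these settings. No setting had a larger offset. Here too, a smaller offset could only move the median further from 0. A further check asked where the remaining cell cycle signal of GCT-OCL came from, not why it was lower. If leftover marrow cells in the proportions of the NBM array brought all of it, the genes would fall with the erythroid list. Of 27 members, 19 lay above that level by more than the SD between probes, and 22 above the level of the neutrophil list. At the level of the B cell, the T and NK cell or the megakaryocyte list 1 of 27 did, and at that of the stem and progenitor list 0. The medians of these lists (-1.63, -1.62, -1.27 and -0.46) lay above the cell cycle median of -1.94. These low counts therefore followed from the medians and say nothing about which cells were left. The offset also shrinks the medians of dim lists, which raises these levels. Leftover cells in other proportions than in NBM stay open. A lower share of dividing cells in the multinucleated preparation, which the design names, stays open and untested.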
